A study of Homo sapiens with 6 samples.

How the data were processed

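RNA of SAS cells, an established human oral squamous cell carcinoma line, was measured on 6 Affymetrix arrays. Per the labels' protocols, cells transfected with a control siRNA or an siRNA against CYLD grew for 2 days and were then kept for 48 h without serum, either with DMSO or with an inhibitor of ALK5, the TGF-β type I receptor. Total RNA was purified on RNeasy columns and 2 µg of it was converted to biotinylated cRNA. The deposited values were 1 intensity per probe set and array on a linear scale, called signal below, and were made with MAS5 per the submitters' processing notes. The MAS5 version was not given in the sources used here. The mean signal after trimming 2% of values at each end was 500.1 on each of the 6 deposited columns, so the arrays stood on a common level before any further step. Median signals per array ran from 73.4 to 84.8. Array data carry no read depth, and the number of arrays limits the precision.

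Arrays were grouped by their titles into untreated siCtrl (2 arrays), untreated siCYLD (2), siCtrl with inhibitor (1) and siCYLD with inhibitor (1). Untreated here means 48 h with DMSO and no inhibitor. For 2 arrays the title and the source name disagreed: siCYLD replicate 1 had a source name for the control siRNA, and siCtrl replicate 2 a source name for the CYLD siRNA. Groups followed the titles whatever the data showed, and the counts of changed genes were repeated with the source names. By source name each untreated group held 1 array titled siCtrl and 1 titled siCYLD, which splits them by replicate number. The knockdown count and the inhibitor count across both siRNAs were also repeated without both arrays, by the additive model for both, which was not run for the interaction or for the inhibitor within each siRNA. The labels do not say whether duplicates were separate cultures.

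Of 54675 probe sets, 62 were array controls, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Entrez identifiers of 41043 were found in the human RefSeq gene table, which changed 0 symbols. Signals were used as log2(signal + 16.06), the offset being the 20th percentile of all values, with no further scaling. A probe set was kept if the highest of its 4 group means lay above the median of all log2 values, which corresponds to a signal of 79.3. Of the probe sets with 1 symbol, 24537 were kept. Each gene was represented by its kept probe set of highest mean, which gave 12935 genes of 19775 on the array. Fold changes are on this offset scale and understate changes of genes near the floor. Probe sets with no symbol or several symbols entered no gene test. No coordinates were used, since no genome build was given in the sources used here.

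Linear models were fitted with limma 3.58.1 in R 4.3.3 with the data.table package at version 1.17.8, with moderated statistics that follow the intensity trend and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05, two-sided. The knockdown difference (untreated siCYLD minus untreated siCtrl), the knockdown by inhibitor interaction and the inhibitor effect within each siRNA came from a model of 4 group means with 2 residual degrees of freedom, to which the moderation added 10.9 prior degrees of freedom. The inhibitor effect across both siRNAs came from an additive model of siRNA and inhibitor with 3 residual and 7.98 prior degrees of freedom. Each lone inhibitor array was assumed to vary as the duplicates did. The siCYLD minus siCtrl difference within the inhibitor pair was reported as values without a p. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

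Before the data were examined, 22 gene lists were fixed: TGF-β targets, TGF-β pathway components, BMP and SMAD1/5 targets, NF-κB targets, NF-κB pathway components with CYLD substrates or partners, mesenchymal genes, epithelial junction and identity genes, squamous differentiation genes, extracellular matrix, protease and adhesion genes, AP-1, immediate early and ERK feedback genes, Wnt targets, YAP/TAZ targets, proliferation genes, p53 targets, interferon-stimulated genes, unfolded protein and integrated stress response genes, cholesterol and fatty acid synthesis genes, hypoxia and glycolysis genes, NRF2 genes, heat shock and proteasome genes, fibroblast markers, and leukocyte and endothelial markers. Lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. They were also tested with fry, which asks whether the members move one way on balance. Camera with an estimated correlation uses only the residual degrees of freedom. A call lost there therefore need not reflect correlated genes. The list test of the interaction was added after the data were seen. For the inhibitor pair, a list median was ranked among the medians of 10000 random lists of equal size matched on mean expression.

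The genes named were also fixed by a rule set at that time. They were CYLD; the 12 largest rises and 12 largest falls of the knockdown among called genes whose 4 untreated arrays did not overlap between groups; the 12 largest of each direction for the inhibitor among called genes whose inhibitor array lay on the same side of both untreated arrays for each siRNA; the 5 largest called interactions of each direction; and up to 4 members of each list by size among called members. The persistence of the knockdown difference under the inhibitor was measured on the 100 highest and 100 lowest genes of 1 untreated array pair, and compared between the other untreated pair and the inhibitor pair, which shared no array with the selection.

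On simulated arrays of the same layout with 12935 genes and 200 changed ones, the knockdown test recovered 75.8% of changes of 1 log2 unit and 93% of changes of 2, with 4.25% false calls. For the inhibitor test these values were 82.2%, 97.4% and 4.93%, and for the interaction 36.2%, 80.8% and 4.89%. For the inhibitor in siCtrl cells they were 69.6%, 92.2% and 6.09%, and in siCYLD cells 67.4%, 92.4% and 3.64%. In 20 simulated draws over 22 lists, camera made 0 calls among unchanged lists and called a list shifted by 0.5 in 20 of 20. Genes were drawn independently, so these draws do not cover lists of correlated genes. Proliferation genes had an estimated correlation of 0.2 for the knockdown and 0.79 for the inhibitor. All simulations took the spread from limma's own fit, alike for all 6 arrays, so a more variable lone array was not covered.

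Alternatives covered quantile normalization, median centring, the offset, the filter, the moderation without trend and in its robust form, the mean of probe sets, leaving out probe sets ending in _x_at or _s_at, the source-name grouping, each array left out in turn, the replicate number as a block, only the untreated arrays, the additive model for the knockdown and the group-mean model for the inhibitor. Dropping both arrays with conflicting labels was added after the data were seen.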

Results

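CYLD encodes a deubiquitinase that removes ubiquitin chains from several signalling adaptors and restrains NF-κB. Its knockdown in SAS oral squamous carcinoma cells was profiled on 6 arrays. There were 2 untreated siCtrl arrays, 2 untreated siCYLD arrays and 1 array of each siRNA after 48 h with an inhibitor of ALK5, the TGF-β type I receptor. Cells called untreated had DMSO in place of the inhibitor. Duplicate arrays correlated at 0.9867 (siCtrl) and 0.988 (siCYLD), and untreated siCtrl and siCYLD arrays at 0.9636 to 0.9661. The array titled siCYLD replicate 1 had a source name for the control siRNA, and the array titled siCtrl replicate 2 had one for the CYLD siRNA. Groups followed the titles throughout. The p-values measure only the spread between these arrays, which may be technical, since the labels do not say that duplicates were separate cultures.

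CYLD itself fell with its siRNA. Of its 7 probe sets, 4 passed the expression filter, and all 4 were lower in untreated siCYLD arrays (adjusted p under 0.05, limma), with 19% to 59.5% of the siCtrl signal left. The most reduced probe set read 485 and 550 in siCtrl and 77.2 and 125 in siCYLD (log2 difference -2.21, 2 arrays each). In the inhibitor pair it read 421 and 71.1, so that 16.9% was left. The brightest probe set, which represented the gene, fell by 0.80 on the log2 scale with a standard error of 0.18 (adjusted p = 0.0065). Without siCtrl replicate 2 that difference was -0.66 with an adjusted p of 0.0589. The 3 probe sets below the filter had differences of -0.50, -0.27 and -0.12 and were not tested. The CYLD signals and the correlations between arrays both went with the titles rather than the source names, although the grouping was not chosen from them.

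**Figure D1:**
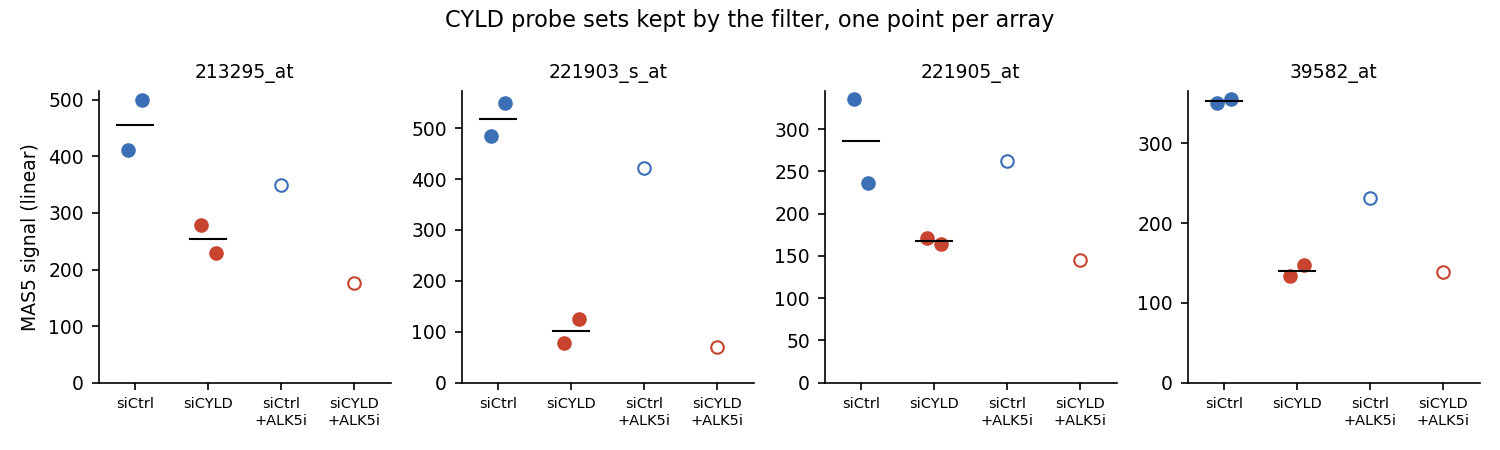
MAS5 signal on a linear axis of the 4 CYLD probe sets that passed the filter, by siRNA and inhibitor of the array title, with bars at the mean of duplicates. Each point is 1 array, and the most reduced probe set read 485 and 550 in untreated siCtrl and 77.2 and 125 in untreated siCYLD.

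With the CYLD siRNA, transcripts of FN1, INHBA, VEGFC and a set of protease genes rose. The array titles name no second CYLD siRNA and no rescue. Effects of the siRNA on other targets therefore cannot be told apart from CYLD loss, here or below. FN1, which encodes the matrix protein fibronectin, rose by 6.57 ± 0.13 (log2 ± standard error, 2 arrays against 2), from signals of 226 and 177 to 20900 and 20200, and its 5 other kept probe sets had differences of 0.84 to 8.48. Without probe sets ending in _x_at or _s_at, FN1 was represented by the probe set at 0.84 and lost its call (adjusted p = 0.186, limma). SGK1, a serum- and glucocorticoid-regulated kinase, rose by 4.59 ± 0.13. INHBA, which encodes the activin A subunit, rose by 3.76 ± 0.12, from 368 and 405 to 5860 and 5060. PMEPA1, a feedback inhibitor of TGF-β signalling, rose by 3.68 ± 0.12, and the lymphangiogenic factor VEGFC by 3.51 ± 0.10, from 1020 and 983 to 11200 and 12000. ARHGAP22 rose by 2.92 ± 0.32 and the cytokine gene IL32 by 2.85 ± 0.36. The gelatinase gene MMP9 rose by 2.75 ± 0.18 and the collagenase gene MMP1 by 2.75 ± 0.41, the latter from signals at the floor of 1.23 and 22 to 175 and 139. TIE1 (3.06 ± 0.58), MSC-AS1 (3.02 ± 0.34) and SCG5 (2.95 ± 0.38) were also among the 12 largest rises. In the inhibitor pair they differed by 0.17, 0.19 and -0.38. An additive fit averages in that pair, and with more weight where untreated arrays are left out. In it their values were 2.10, 2.08 and 1.84 with all 6 arrays and were called. In the same fit without both arrays with conflicting labels they were 1.56, 1.71 and 1.05 and not called (adjusted p of 0.374, 0.111 and 0.333).

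Among the largest falls were those of COL8A1, TNNI2 and SCEL. COL8A1, a collagen chain, fell by 4.20 ± 0.36 on the log2 scale, from signals of 378 and 429 to 9.63 and 4.27. The troponin gene TNNI2 fell by 3.84 ± 0.30, and SCEL, which encodes the cornified envelope protein sciellin, fell by 3.72 ± 0.15, from 2320 and 2090 to 159 and 144. The mitotic kinesin gene KIFC1 fell by 3.04 ± 0.25, the atypical cadherin gene FAT4 by 2.73 ± 0.22, ABI3BP by 2.69 ± 0.26 and PRR16 by 2.64 ± 0.31. NANOS1 fell by 2.54 ± 0.09, the collagen-modifying enzyme gene P3H2 by 2.45 ± 0.15, the neurotrophin receptor gene NGFR by 2.33 ± 0.16 and the cytokinesis gene ANLN by 2.31 ± 0.17. CKAP2L, a spindle protein gene, fell by 3.10 ± 0.30, and in the inhibitor pair it differed by 0.14. Its additive-fit value was -2.02 with all 6 arrays, which was called, and -1.51 without both arrays with conflicting labels, which was not (adjusted p = 0.0898).

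Of 12935 genes tested with limma, 2757 changed with the knockdown, 1227 higher and 1530 lower, and 252 and 301 of these changed at least 2-fold. At unadjusted p under 0.05 there were 4420. The 4 untreated arrays did not overlap between groups for 7875 genes (60.9%, with 33.3% by chance alone). An additive fit of all 6 arrays called 2787 genes, and without both arrays with conflicting labels it called 963, 463 higher and 500 lower, of which 898 were also among the 2757. The smaller fit weighs the inhibitor pair more, so its count does not test the labels alone. Grouped by source names, which splits the untreated arrays by replicate number, the test called 0 genes, with 104 at unadjusted p under 0.05. A difference between titles cancels in that grouping, so its count does not test the difference. Without the intensity trend the titled groups gave 1219 calls.

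Proliferation genes fell as a group. Of 51 tested, 49 were lower and 0 higher (49 and 0 adjusted over the list alone), and the median log2 difference was -1.39. CCNB2, the cyclin B2 gene, fell by 2.25 ± 0.17 from signals of 1040 and 1420 to 281 and 209. Its 1 other kept probe set did not share this direction. The kinase gene TTK fell by 2.10 ± 0.18 and the topoisomerase gene TOP2A by 2.06 ± 0.13. MKI67 signals went from 563 and 662 to 220 and 172. KIF20A fell by 2.13 ± 0.42, and in the inhibitor pair it differed by -0.15. In the additive fit it had -1.47 with all 6 arrays, which was called, and -1.36 without both arrays with conflicting labels, which was not (adjusted p = 0.142). Its call was also lost without the intensity trend (adjusted p = 0.061). The list gave an adjusted p of 1.7e-33 with limma's camera, and an adjusted p = 0.15 with an estimated correlation. The ACTB 3'/5' ratio and the poly-A spike controls differed between the same groups of arrays. The ACTB 3'/5' ratio was 3.41, 3.21 and 3.67 in the siCtrl arrays and 2.26, 2.48 and 2.38 in the siCYLD arrays, the last of each being the inhibitor array. The GAPDH ratio overlapped between them, at 2.14, 1.79 and 1.87 in siCtrl and 1.8, 1.91 and 1.97 in siCYLD. Poly-A spike controls were higher in siCYLD by medians of 0.402, 0.185 and 0.359 in the 3 pairs.

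Targets of TGF-β rose. Of 41 tested, 27 were higher and 2 lower (30 and 2 adjusted over the list alone), with a median of 0.73. Beside FN1, PMEPA1 and MMP9, TGFBI, which encodes a secreted adhesion protein, rose by 1.72 from signals of 8050 and 9530 to 29200 and 28400, and the cytokine gene IL11 by 1.04. ANGPTL4 rose by 2.27 ± 0.42. Its additive-fit value was 1.91 with all 6 arrays, which was called, and 1.88 without both arrays with conflicting labels, which was not (adjusted p = 0.0933). The list had an adjusted p of 1.2e-18 (camera), and adjusted p = 0.11 with an estimated correlation. That estimate was -0.00061, below the preset 0.01, so correlated genes did not account for the lost call. Components of the TGF-β pathway also rose, with 12 higher and 2 lower of 31 (12 and 4 adjusted over the list alone), a median of 0.17, an adjusted p of 0.00041 and adjusted p = 0.15 with an estimated correlation. After INHBA, the largest were the ligand gene TGFB1 (0.96 ± 0.12, from 1040 and 1030 to 2140 and 1940), the integrin gene ITGAV (0.84 ± 0.10) and the co-receptor gene ENG (0.81 ± 0.17). In the additive fit ITGAV and ENG had 0.61 and 0.66 with all 6 arrays, which were called, and 0.53 and 0.51 without both arrays with conflicting labels, which were not (adjusted p of 0.0987 and 0.188). In the inhibitor pair ITGAV and ENG differed by 0.16 and 0.35. The ENG call was also lost for the mean of probe sets (0.72, adjusted p = 0.0538).

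Targets of NF-κB rose, 24 of 35 being higher and 0 lower (25 and 0 adjusted over the list alone), with a median of 0.99. CXCL8, a neutrophil chemokine gene, rose by 2.00 ± 0.29 from signals of 60.2 and 38.1 to 277 and 209. CXCL2 rose by 1.75 ± 0.10 and TNFAIP3, which encodes the NF-κB feedback inhibitor A20, by 1.63 ± 0.11 from 668 and 610 to 1980 and 2030. IL1B rose by 1.37, from 751 and 888 to 2210 and 2080. The list had an adjusted p of 1.1e-16 (camera), and adjusted p = 0.11 with an estimated correlation. Pathway components and CYLD partners were not called as a list, with 5 higher and 3 lower of 33 (9 and 4 adjusted over the list alone). The lower members included CYLD itself, the target of the siRNA, and PLK1 (-0.88), which also stands in the proliferation list. Of the higher members, the kinase gene IKBKE rose by 0.86.

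Matrix, mesenchymal and AP-1 genes also rose. Of 48 matrix, protease and adhesion genes, 28 were higher and 5 lower (28 and 6 adjusted over the list alone), with a median of 0.48, an adjusted p of 2.6e-11 (camera) and adjusted p = 0.11 with an estimated correlation. The stromelysin gene MMP10 rose by 2.43 ± 0.39 and the anchoring collagen gene COL7A1 by 1.92, from 1080 and 972 to 3990 and 3860, while the metalloprotease inhibitor gene TIMP3 fell by 1.88, from 3000 and 3250 to 778 and 897. Of 37 mesenchymal genes, 15 were higher and 2 lower (16 and 4 adjusted over the list alone), with a median of 0.27, an adjusted p of 9.2e-06 and adjusted p = 0.15 with an estimated correlation. Of 33 AP-1, immediate early and ERK feedback genes, 16 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.31, an adjusted p of 7.8e-09 and adjusted p = 0.15 with an estimated correlation. LIF (1.56 ± 0.11), DUSP4 (1.22 ± 0.13), ETV4 (1.10 ± 0.19) and KLF6 (1.03 ± 0.09) were its largest rises, and the ETV4 call was lost without the intensity trend (adjusted p = 0.0721). The TGF-β target list shared 7 tested genes with the matrix list, 8 with the mesenchymal list and 1 with the NF-κB target list. In all, 7 of 22 lists were called at the preset correlation and 0 with an estimated one (7 at unadjusted p under 0.05), and fry called 9. All 7 held in the additive fit without both arrays with conflicting labels.

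**Figure D2:**
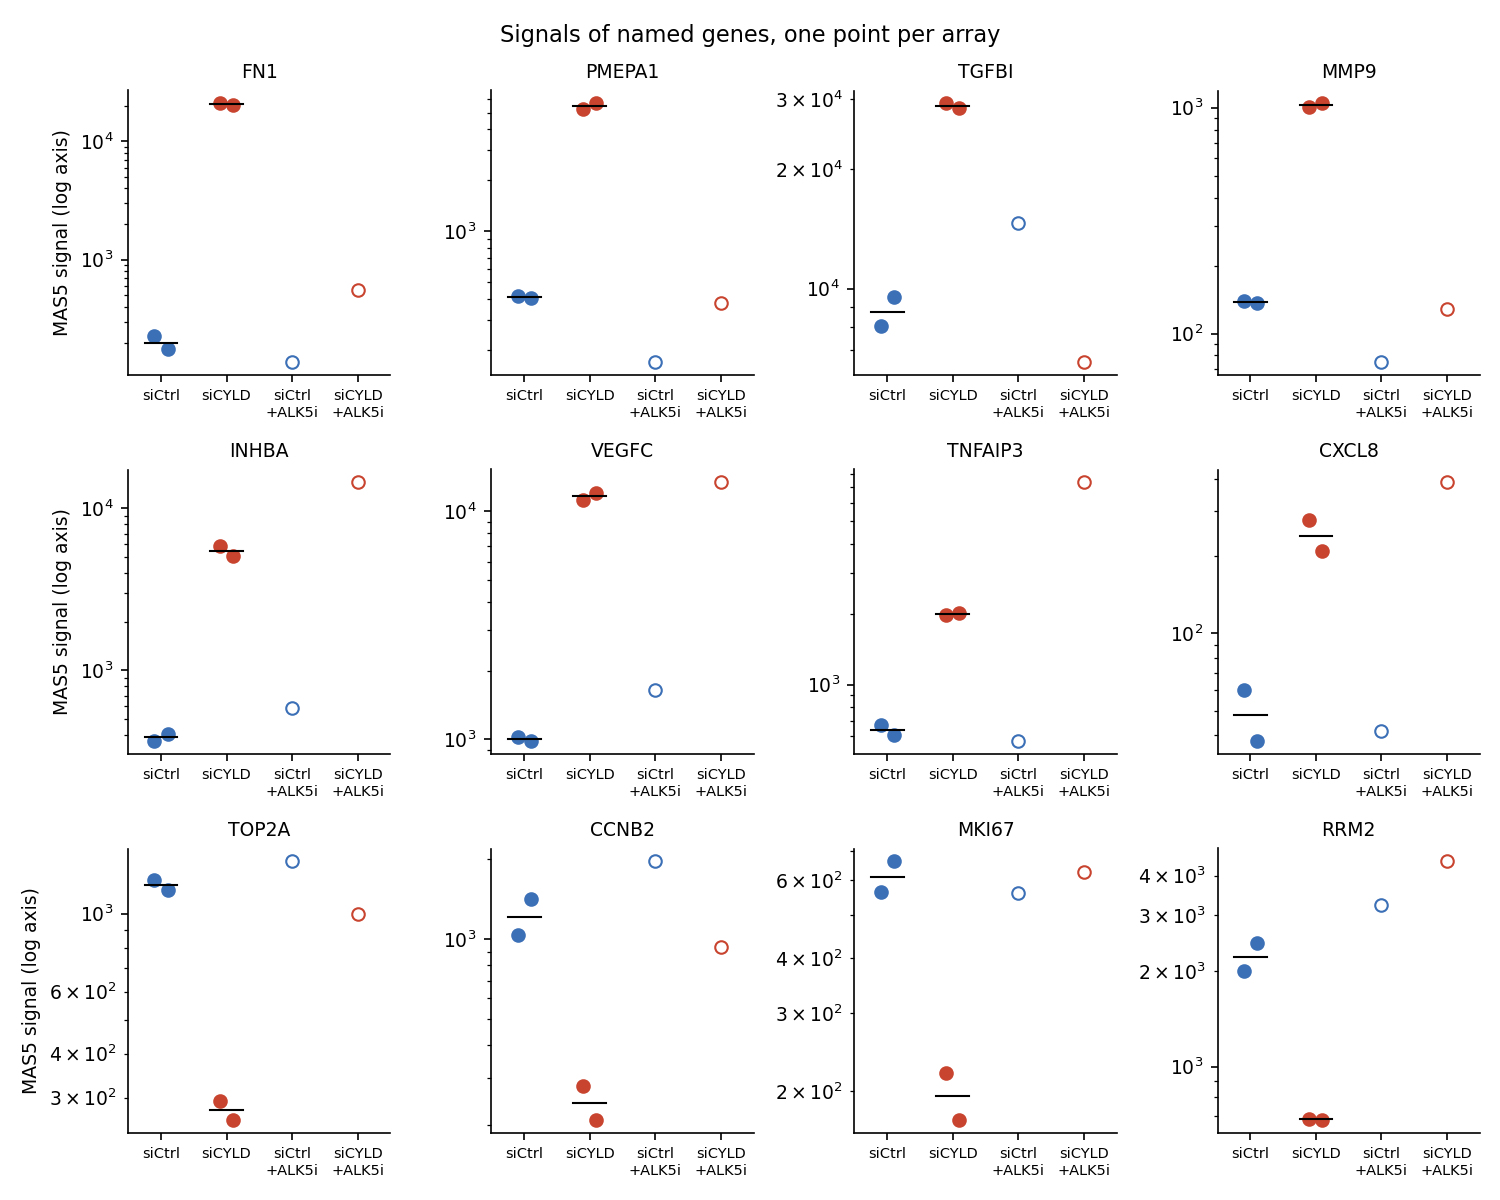
MAS5 signals of 12 genes on log axes, in the 4 groups of siRNA and inhibitor, with 1 point per array and bars at the geometric mean of duplicates. FN1 read 226 and 177 in untreated siCtrl, 20900 and 20200 in untreated siCYLD, and 137 and 558 in the inhibitor pair.

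The other lists were not called by camera for the knockdown, although single members changed. Of them, fry called the BMP and SMAD1/5 targets (adjusted p = 0.03) and the epithelial genes (adjusted p = 0.043). Squamous differentiation genes split, 4 higher and 5 lower of 23 (5 and 5 adjusted over the list alone), with SCEL lower and the gap junction gene GJB2 higher by 2.55, from 385 and 347 to 2230 and 2190. Epithelial junction and identity genes were 5 higher and 12 lower of 48 (7 and 15 adjusted over the list alone), and the epithelial transcription factor gene ELF3 fell by 0.79. Wnt targets were 2 higher and 3 lower of 13 (4 and 3 adjusted over the list alone), with the Wnt antagonist gene DKK1 at -1.29 and SOX9 at 1.08. YAP/TAZ targets were 2 higher and 4 lower of 21 (2 and 6 adjusted over the list alone), AJUBA and MYOF falling by 0.87 and 0.81. Among 11 BMP and SMAD1/5 targets, 1 was higher and 0 lower (1 and 0 adjusted over the list alone), DLX2 at 0.93. Hypoxia and glycolysis genes were 5 higher and 5 lower of 33 (5 and 6 adjusted over the list alone), with NDRG1 at 1.34 and ADM at -1.04.

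The lists of stress, metabolic and cell type genes were also not called by camera. Adjusted over the list alone, the lists of this paragraph gave the same counts as over all genes. p53 targets were 2 higher and 4 lower of 24, with PLK3 at 1.24 and PLK2 at -1.19. Interferon-stimulated genes were 4 higher and 6 lower of 34, with IFIT2 at -1.45. Unfolded protein and integrated stress response genes were 1 higher and 7 lower of 33, the serine synthesis gene PHGDH falling by 1.16 and EDEM1 by 0.90. NRF2 genes were 2 higher and 6 lower of 21, with GCLC at -0.88 and TXNRD1 at -0.60. Cholesterol and fatty acid synthesis genes were 0 higher and 3 lower of 23 (6 at unadjusted p under 0.05, limma), with INSIG1 at -0.70. Heat shock and proteasome genes were 2 higher and 1 lower of 26. Among fibroblast markers 0 were higher and 1 lower of 6 (2 at unadjusted p under 0.05), FBLN1 at -1.17, and among leukocyte and endothelial markers 0 of 6 were called (0 at unadjusted p under 0.05).

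The ALK5 inhibitor raised KRT5, a basal keratin gene, and lowered CST6, IL11, FOS and EGR1. Differences are across both siRNAs, from 2 inhibitor arrays and 4 untreated ones. KRT5 rose by 2.98 ± 0.16, from 1090 and 1250 to 12500 in siCtrl cells and from 900 and 968 to 5600 in siCYLD cells. THBD, which encodes thrombomodulin, rose by 2.54 ± 0.12, the insulin receptor substrate gene IRS1 by 2.25, NGFR by 2.27, IGFBP2 by 2.61 and SHISA2 by 2.39. IFIT2 rose by 2.78 ± 0.25, CDH5 by 3.30 ± 0.42 and ZNF488 by 2.65. CST6, which encodes a cysteine protease inhibitor, fell by 3.64 ± 0.32, from 1140 and 1420 to 189 in siCtrl cells and from 4900 and 4860 to 182 in siCYLD cells. IL11 fell by 2.66 ± 0.15, FOS by 2.51 ± 0.26, PMEPA1 by 2.5 ± 0.41, EGR1 by 2.19 ± 0.13 and ADTRP by 2.06. The PMEPA1 call was lost with the robust moderation (adjusted p = 0.0727, limma). Less described transcripts that fell were MIR181A2HG (-2.58), ZFHX4-AS1 (-2.53) and TMEM190 (-2.34).

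Some of the largest inhibitor differences lost their call when arrays were left out. Without the siCYLD inhibitor array the fit measured the inhibitor in siCtrl cells alone. Calls lost there therefore also reflect the difference between the siRNAs. FN1 fell by 2.83 ± 0.71, but its fall was -5.16 in siCYLD cells and -0.49 in siCtrl cells (adjusted p = 0.076, limma), and its call was lost without the siCYLD inhibitor array (-0.49, adjusted p = 0.0672) and without untreated siCYLD replicate 2 (-2.5, adjusted p = 0.0553). It was also lost without probe sets ending in _x_at or _s_at (-1.23, adjusted p = 0.0537), with no filter (adjusted p = 0.0599), without the intensity trend (adjusted p = 0.118) and with the robust moderation (adjusted p = 0.249). Without the siCYLD inhibitor array the calls of FAM81A (2.36, then 1.91, adjusted p = 0.125), MMP10 (2.26, then 1.73, adjusted p = 0.124), CRCT1 (-2.43, then -1.45, adjusted p = 0.089) and FAP (-2.08, then -1.60, adjusted p = 0.0864) were lost. CCL20 (2.28) was lost without untreated siCYLD replicate 1 (2.10, adjusted p = 0.0765), without untreated siCYLD replicate 2 (2.06, adjusted p = 0.0799) and without untreated siCtrl replicate 1 (2.45, adjusted p = 0.0502). Without both arrays with conflicting labels the CCL20 (2.34, adjusted p = 0.0596) and FAP (-2.24, adjusted p = 0.0546) calls were lost although the differences did not shrink. The CCL20 call was also lost with no offset (3.43, adjusted p = 0.0793), without the intensity trend (adjusted p = 0.0699) and for the mean of probe sets (adjusted p = 0.0537). With no filter FAM81A was represented by another probe set and turned to -0.14.

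With the inhibitor 2586 of 12935 genes changed, 1445 higher and 1141 lower, and 241 and 152 of them at least 2-fold. At unadjusted p under 0.05 there were 4413. Median centring moved the share of higher genes among calls from 55.9% to 71.2%. Without the siCYLD inhibitor array the fit measured siCtrl cells alone, so that count also reflects the difference between the siRNAs. The count was 1265 without the siCYLD inhibitor array, 1539 without untreated siCYLD replicate 1, 1654 without untreated siCYLD replicate 2 and 1710 without untreated siCtrl replicate 1. Without both arrays with conflicting labels it was 1257, 784 higher and 473 lower. Within siCtrl cells 1211 genes changed, 649 higher and 562 lower, and within siCYLD cells 2900, 1578 higher and 1322 lower, each from 1 array against 2. In siCtrl cells median centring moved the higher share from 53.6% to 71.9%. Without the intensity trend the inhibitor counts were 1087 across both siRNAs, 35 in siCtrl and 1055 in siCYLD cells. With no filter on low values they were 478 in siCtrl and 1819 in siCYLD cells. Grouped by source names limma called 27 genes across both siRNAs, and 0 in siCtrl and 0 in siCYLD cells (1206 and 1420 at unadjusted p under 0.05). That grouping mixes both titles in each untreated group, so the difference between titles adds to the spread and lowers the counts. These counts therefore do not test the inhibitor effect under the titles. The inhibitor differences of siCtrl and siCYLD cells, which shared no array, correlated at 0.497 over all genes.

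Proliferation genes rose with the inhibitor. Of 51 tested, 43 were higher and 0 lower (48 and 0 adjusted over the list alone), with a median of 1, an adjusted p of 4.6e-20 (camera) and adjusted p = 0.60 with an estimated correlation. The median was 0.45 in siCtrl cells and 1.60 in siCYLD cells. TYMS, the thymidylate synthase gene, rose by 1.66 and RRM2, a ribonucleotide reductase subunit gene, by 1.61, although the RRM2 call was lost with the robust moderation (adjusted p = 0.115) and without the intensity trend (adjusted p = 0.0811). CDK1 (1.32) and MCM10 (1.38) lost their calls without the siCYLD inhibitor array, at 0.58 (adjusted p = 0.0747) and 0.88 (adjusted p = 0.0597), and CDK1 also without the intensity trend (adjusted p = 0.0652).

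Targets of TGF-β fell with the inhibitor, 3 being higher and 17 lower of 41 (5 and 19 adjusted over the list alone), with a median of -0.37, an adjusted p of 0.0021 (camera) and adjusted p = 0.67 with an estimated correlation. The median was -0.12 in siCtrl cells and -0.69 in siCYLD cells, and without the siCYLD inhibitor array the list was not called (-0.12, adjusted p = 0.641). Unfolded protein and integrated stress response genes fell slightly, 3 being higher and 6 lower of 33 (the same adjusted over the list alone), with a median of -0.15, an adjusted p of 0.049 and adjusted p = 0.60 with an estimated correlation. That call was lost without untreated siCYLD replicate 1 (-0.16, adjusted p = 0.0529), untreated siCtrl replicate 2 (-0.14, adjusted p = 0.156), the siCtrl inhibitor array (-0.12, adjusted p = 0.229) and both arrays with conflicting labels (-0.13, adjusted p = 0.183). At the preset correlation 3 lists were called, with an estimated one 0 (0 at unadjusted p under 0.05), and by fry 4. The fry calls were squamous (adjusted p = 0.018), interferon-stimulated, unfolded protein and NRF2 genes (adjusted p = 0.031 each), while proliferation genes (adjusted p = 0.094) and TGF-β targets (adjusted p = 0.16) were not called by fry.

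The remaining lists were not called by camera and split in both directions with the inhibitor. The early genes FOS, EGR1 and DUSP1 (-1.26) fell while DUSP6 rose by 1.18, and AP-1, immediate early and ERK feedback genes were 10 higher and 6 lower of 33 (10 and 8 adjusted over the list alone). TGF-β pathway components were 5 higher and 7 lower of 31 (7 and 8 adjusted over the list alone), the corepressor gene SKIL falling by 1.64 and TGFB1 by 1.08 while TGFB2 rose by 1.13. Matrix genes were 10 higher and 12 lower of 48 (11 and 13 adjusted over the list alone), with TIMP3 at 1.99. Squamous genes were 4 higher and 9 lower of 23 (4 and 11 adjusted over the list alone), with GJB2 at 1.28 and SCEL at -1.25. NF-κB targets were 6 higher and 4 lower of 35 (6 and 5 adjusted over the list alone), with LCN2 at -1.83 and IL1B at 1.33. Epithelial genes were 5 higher and 8 lower of 48 (5 and 11 adjusted over the list alone), BMP and SMAD1/5 targets 3 and 2 of 11 (5 and 3), Wnt targets 3 and 3 of 13 (5 and 3) and p53 targets 2 and 6 of 24 (2 and 9). Among their members ID2 fell by 1.36, HEY1 by 1.24 and CDKN1A by 1.20, while RNF43 rose by 1.02.

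Interferon-stimulated genes were 8 higher and 5 lower of 34 with the inhibitor (9 and 7 adjusted over the list alone), IFIT3 rising by 1.59 and TRIM22 by 1.23. Hypoxia genes were 5 higher and 5 lower of 33 (6 and 6 adjusted over the list alone), with LOX at 1.36 and ADM at 1.16. For the lists that follow, the counts adjusted over the list alone were the same as over all genes. YAP/TAZ targets were 5 higher and 5 lower of 21, CCN2 falling by 1.61. Mesenchymal genes were 5 higher and 6 lower of 37, and NF-κB pathway components 3 higher and 4 lower of 33. NRF2 genes were 1 higher and 5 lower of 21, with NQO1 at -1.20 and HMOX1 at -0.97, and heat shock and proteasome genes 1 higher and 4 lower of 26, with DNAJB1 at -0.69. Without the siCtrl inhibitor array the NRF2 list was called (-0.22, adjusted p = 0.0408), and without untreated siCYLD replicate 2 the heat shock list was (-0.12, adjusted p = 0.0487). Cholesterol genes were 5 higher and 2 lower of 23, fibroblast markers 1 and 1 of 6, and leukocyte and endothelial markers 2 and 1 of 6.

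For TGFBI, PTX3 and FN1 the knockdown difference was called as dependent on the inhibitor. An error of either lone inhibitor array cannot be told apart from such a dependence, and without the intensity trend 0 interactions were called. The interaction compares the siCYLD minus siCtrl difference with and without inhibitor. FN1 had the largest negative value (-4.67 ± 0.23), its signals being 137 and 558 in the inhibitor pair. Without probe sets ending in _x_at or _s_at its interaction was -1.03 and not called (adjusted p = 0.595, limma). TGFBI, raised by the knockdown without inhibitor, read 14600 and 6550 with it (-2.87 ± 0.16). FAXDC2 (-3.42 ± 0.57), SCG5 (-3.32 ± 0.66) and SLC47A2 (-3.00 ± 0.57) lay between FN1 and TGFBI in size. FAXDC2 had widely spread duplicates of 1100 and 579 in siCtrl and 485 and 1160 in siCYLD. For the mean of probe sets FAXDC2 had -0.97 (adjusted p = 0.341), and the SCG5 call was also lost (adjusted p = 0.0569). Of the positive values CKAP2L had 3.24 ± 0.51, the pentraxin gene PTX3 2.95 ± 0.26 and ESPN 2.58 ± 0.39. LINC01504 (2.76 ± 0.61) lost its call without untreated siCtrl replicate 1 (2.49, adjusted p = 0.0591, limma). SYT15 (2.61 ± 0.55) was represented by another probe set without untreated siCtrl replicate 1 or 2, at -0.76 and -0.74, and was then not called.

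For the interaction 216 genes were called, 127 positive and 89 negative, with 97 and 62 at least 2-fold and 1767 at unadjusted p under 0.05. The count was 458 without untreated siCYLD replicate 1, 362 without untreated siCYLD replicate 2 and 343 without untreated siCtrl replicate 1. It was 135 under median centring, 134 without probe sets ending in _x_at or _s_at, 95 for the mean of probe sets and 33 with no filter on low values. Without the intensity trend limma called 0, with 1480 at unadjusted p under 0.05, and grouped by source names it also called 0, with 524 at unadjusted p under 0.05. The source-name grouping mixes both titles in each untreated group, so its count does not test the interaction under the titles. Each interaction value contains 2 single inhibitor arrays, which were assumed to vary as the duplicates did.

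Proliferation genes had the most positive interactions, 18 positive and 0 negative of 51 (41 and 0 adjusted over the list alone), with a median of 1.13, an adjusted p of 6.6e-33 (camera) and adjusted p = 0.44 with an estimated correlation. RRM2 (2.13) read 2000 and 2450 in siCtrl and 686 and 679 in siCYLD, and 3230 and 4430 with the inhibitor. TPX2 had 1.76, BIRC5 1.75 and MKI67 1.73, the calls of TPX2 and BIRC5 being lost for the mean of probe sets (adjusted p of 0.0708 and 0.0602). TGF-β targets were 0 positive and 10 negative of 41 (1 and 18 adjusted over the list alone), with a median of -0.46, an adjusted p of 2e-17 and adjusted p = 0.20 with an estimated correlation. NF-κB targets were 5 positive and 1 negative of 35 (13 and 4 adjusted over the list alone), with a median of 0.12, an adjusted p of 0.024 and adjusted p = 0.44 with an estimated correlation. Their median was 0.18 to 0.36 with any 1 untreated array left out. TNFAIP3 (2.01), CXCL1 (1.42) and IL6 (1.04) were positive, TNFAIP3 reading 574 and 7330 with the inhibitor, and MMP9 was negative (-2.09). For the mean of probe sets the CXCL1 and IL6 calls were lost (adjusted p of 0.0845 and 0.0587). Mesenchymal genes were 1 positive and 4 negative of 37 (3 and 8 adjusted over the list alone), and matrix genes 1 and 7 of 48 (2 and 11 adjusted over the list alone). These lists had medians of -0.18 and -0.02 and an adjusted p of 0.024 each, with adjusted p = 0.44 with an estimated correlation. Of the other lists, epithelial genes were 0 positive and 4 negative (0 and 6 adjusted over the list alone), AP-1 genes 3 and 0 (4 and 1 adjusted over the list alone) and hypoxia genes 0 and 3 (1 and 3 adjusted over the list alone), and none was called as a list, the lowest camera adjusted p being 0.13 for p53 targets. In all 5 lists were called at the preset correlation, 0 with an estimated one (2 at unadjusted p under 0.05) and 3 by fry. The fry calls were TGF-β targets, mesenchymal and matrix genes (adjusted p = 0.023 each), while proliferation genes (adjusted p = 0.1) and NF-κB targets (adjusted p = 0.14) were not called by fry.

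**Figure D3:**
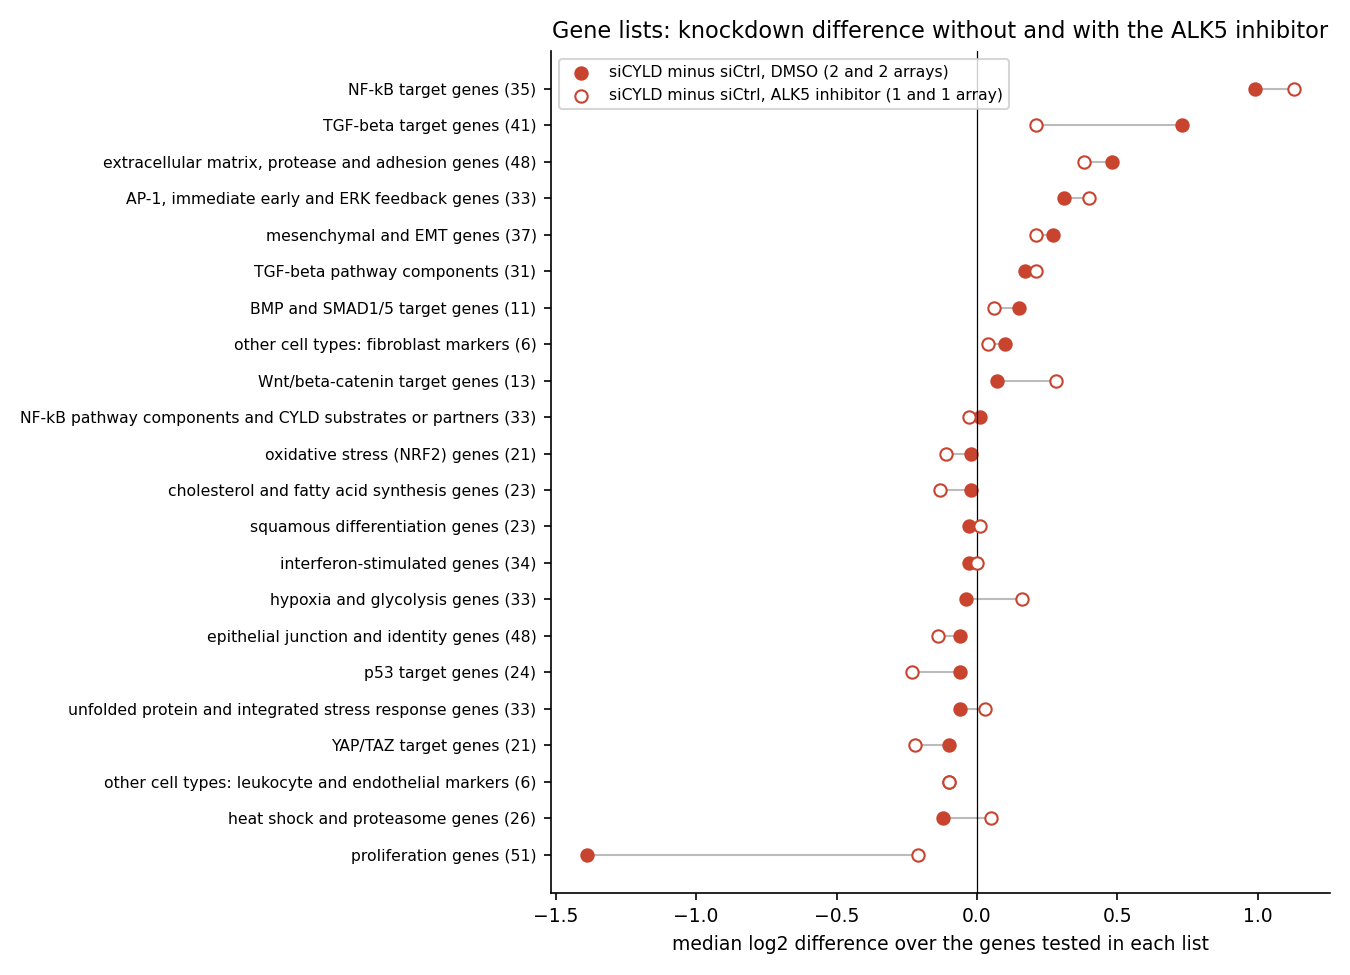
Median log2 difference of siCYLD minus siCtrl over the genes tested in each list, filled for untreated arrays (2 and 2) and open for the inhibitor pair (1 and 1). Proliferation genes lay at -1.39 and -0.21, NF-κB targets at 0.99 and 1.13, and TGF-β targets at 0.73 and 0.21.

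Under the inhibitor, NF-κB targets kept the siCYLD difference while proliferation genes largely lost it. The median of siCYLD minus siCtrl in the inhibitor pair was 1.13 for NF-κB targets, above all 10000 random lists of matched expression (percentile 100). CXCL8 read 41.8 and 388 there, and VEGFC 1650 and 13400. INHBA kept a difference of 4.60, reading 583 and 14500, and MMP1 read 10 and 1190. COL7A1 had no difference left, at 929 and 928, nor TIMP3, at 6490 and 6490. PMEPA1 read 170 and 377, and MMP9 74.9 and 128. Proliferation genes had a median of -0.21 (percentile 0.45), TOP2A reading 1410 and 995 and CCNB2 1970 and 937. TGF-β targets had 0.21 (percentile 99.8), their pathway components 0.21 (99.6), matrix genes 0.38 (100), AP-1 genes 0.40 (100) and mesenchymal genes 0.21 (98.8). Below most random lists lay YAP/TAZ targets (-0.22, percentile 0.31), epithelial genes (-0.14, 0.4) and p53 targets (-0.23, 0.87). These are single arrays and no p was computed.

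Most knockdown calls kept their sign under the inhibitor. Of 1227 genes higher with the knockdown, 1094 (89.2%) were also higher in the inhibitor pair, the median going from 0.60 to 0.45. Of 1530 lower genes, 1341 (87.6%) were lower, with medians of -0.59 and -0.39. The smaller medians are in part what selection on the untreated difference gives. To reduce this, the 100 highest genes were picked from 1 untreated pair. Their median in the other untreated pair was 1.61 or 1.65 and in the inhibitor pair 1.02 or 0.98, so 63.5% or 59.5% was kept. For the 100 lowest genes the medians were -1.56 or -1.61 and -0.61 or -0.58, and 38.8% or 36.2% was kept. The labels do not say that duplicates were separate cultures. If they were not, both untreated pairs share culture differences that the inhibitor pair lacks. A smaller median in the inhibitor pair then need not come from the inhibitor. Over all genes the untreated and inhibitor differences correlated at 0.508.

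**Figure D4:**
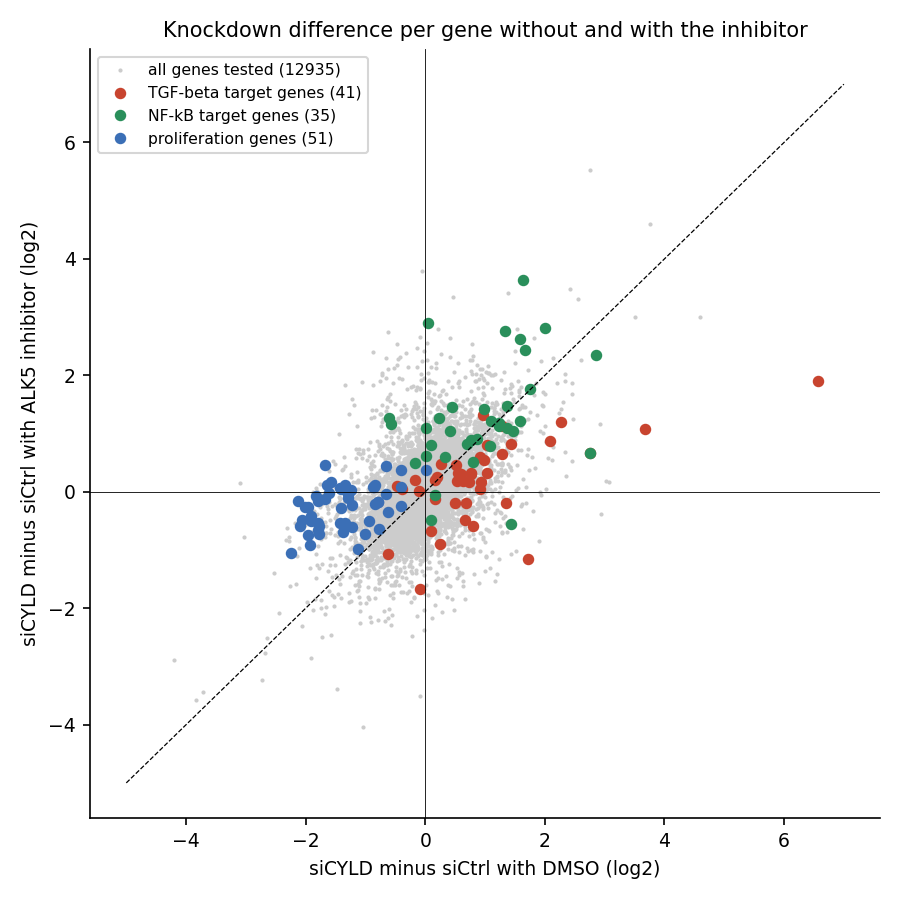
Log2 difference of siCYLD minus siCtrl for each gene tested, without inhibitor (horizontal, 2 and 2 arrays) and with it (vertical, 1 and 1 array). Each point is 1 gene, and the correlation was 0.508.

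Averaged over both siRNAs, the inhibitor tended to move genes against the knockdown. That average includes siCYLD cells, where a loss of the knockdown difference itself counts as a move against it. The inhibitor median was 0.45 in siCtrl and 1.60 in siCYLD cells for proliferation genes, and -0.12 and -0.69 for TGF-β targets. Genes lower with the knockdown and higher with the inhibitor numbered 405, where 171 were expected if the calls were independent (ratio 2.37), and included CCNB2, TIMP3 and NGFR. Genes higher with the knockdown and lower with the inhibitor numbered 221, against 108 expected (2.04), and included PMEPA1, CST6 and IL11. Both rose for 151 genes (137 expected, ratio 1.1) and both fell for 113 (135 expected, 0.837), SCEL among the latter. Over all genes the differences correlated at -0.229 (rank correlation -0.184). In 100 simulations of unchanged groups the mean was 0.0031 with a standard deviation of 0.016. Those simulations hold no knockdown or inhibitor effect. They therefore do not show how far unrelated real effects on correlated genes would correlate.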

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

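The list test of the interaction, the matched draws, the share kept in the inhibitor pair and the comparisons of spike controls were chosen only after the results they examine had been seen. Values are given here because the inhibitor difference was not the same in siCYLD and siCtrl cells, or because they came from probe sets that entered no gene test.

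The inhibitor difference was called as unequal between the 2 siRNA groups for 216 genes (limma), each value resting on 1 inhibitor array per siRNA. At the preset correlation camera also called 5 lists, with medians of -0.46 (TGF-β targets), 0.12 (NF-κB targets), -0.18 (mesenchymal genes), -0.02 (matrix genes) and 1.13 (proliferation genes). With an estimated correlation it called 0 lists, the smallest adjusted p being 0.20 (2 at unadjusted p under 0.05), and fry called 3. Negative values, siCYLD minus siCtrl in log2, belonged to FN1 (-4.67), FAXDC2 (-3.42), SCG5 (-3.32), SLC47A2 (-3.00), TGFBI (-2.87), MSC-AS1 (-2.83), PMEPA1 (-2.60), MIR181A2HG (-2.11), MMP9 (-2.09), CST6 (-1.98), COL7A1 (-1.92), SGK1 (-1.59), PFKFB4 (-1.47), SMAD7 (-1.38), PFKFB3 (-1.30), IGFBP3 (-1.27), PARD6B (-1.07), NDRG1 (-0.96), CDKN1A (-0.94), KRT5 (-0.84), DSP (-0.80) and KRT7 (-0.55). Positive values belonged to EGR1 (0.68), EREG (0.76), PSMB8 (0.84), DNAJB11 (0.86), IL6 (1.04), DKK1 (1.05), NANOS1 (1.15), LOXL2 (1.40), CXCL1 (1.42), CDK1 (1.49), NGFR (1.49), FOS (1.5), TTK (1.52), TYMS (1.56), TOP2A (1.57), ANLN (1.70), MKI67 (1.73), BIRC5 (1.75), TPX2 (1.76), TIMP3 (1.88), TNFAIP3 (2.01), RRM2 (2.13), KIFC1 (2.25), ESPN (2.58), SYT15 (2.61), LINC01504 (2.76), PTX3 (2.95) and CKAP2L (3.24). Among probe sets with no gene symbol or several, 565 of 5612 (10.1%) were called for the knockdown, beside 3902 of 24537 (15.9%) with 1 symbol.

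Targets of TGF-β lost much of the knockdown rise under the inhibitor (median interaction -0.46) and targets of NF-κB did not (0.12). Regression of large knockdown differences toward 0 was tested by drawing genes matched on the knockdown difference, and 0.66% of 10000 draws had a median as low as the TGF-β list. The draws themselves had medians of -0.20 for the TGF-β list (95% range -0.41 to -0.01) and -0.21 for the NF-κB list. The drawn genes were chosen by their knockdown difference, whereas the list was fixed beforehand. The drawn genes can also hold real changes under the inhibitor, so the draws cannot assign any part of the TGF-β loss to regression. With any 1 untreated array left out, the NF-κB median was 0.18 to 0.36. It stayed at least 0.65 above the TGF-β median, so no single untreated array decided the contrast. As a hypothesis, the response to the CYLD siRNA could have an ALK5-dependent and an ALK5-independent part. Repeated inhibitor arrays in both siRNA groups would test it, since an error of either lone inhibitor array stays open.

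Proliferation genes fell with the knockdown and much less so in the inhibitor pair. The list median was -1.31 or lower with any 1 untreated array left out, and -1.34 or lower relative to all genes under quantile normalization or median centring, so neither 1 untreated array nor the scaling accounted for the fall. Neither test covers the smaller difference in the inhibitor pair, for which an error of either lone inhibitor array stays open. In the inhibitor pair the list kept a share of 0.15 of its untreated median while the ACTB 3'/5' shift kept its size (-0.592 and -0.372 untreated, -0.627 with inhibitor), which speaks against RNA quality or labelling as the whole cause but rests on single arrays. As a hypothesis, a slowing of the cell cycle that needs ALK5 signalling could give this pattern, which cell counts and cycle phases with and without inhibitor would test and which were not analysed here.

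Poly-A spike controls read higher on the siCYLD arrays by medians of 0.402, 0.185 and 0.359 in the replicate 1, replicate 2 and inhibitor pairs, all 18 probe sets being higher in each. Brighter hybridisation was tested against the hybridisation controls, over which the poly-A controls stood by at least 0.17 in these pairs and by 0.112 to 0.204 over all 4 pairings of untreated siCYLD with siCtrl arrays. The largest excess was 0.302, which could come from a lower yield of endogenous poly-A RNA in siCYLD cells or from a larger amount of spike, and these were not told apart. Between duplicates of the same siRNA the excess was 0.0859 and 0.0744, little below the lowest pairing of siCYLD with siCtrl, so brightness alone did not account for the shift but the margin was small.

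The 4 untreated arrays can be divided into 3 splits of 2 and 2, too few for a share under 0.05. The split by title gave 2802 calls with limma from the untreated arrays alone, as did 1 of the 3 splits, the split by title itself. The highest count of any other split was 0, with 79 and 62 genes at unadjusted p under 0.05. Every other split mixes both titles in each group. A difference between titles cancels there and adds to the spread, so these low counts are no separate check against chance.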

How the results depend on the processing

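The alternatives without both arrays with conflicting labels were chosen after the results had been seen. A change of sign in a value called under neither setting was not counted as a reversal, and the cause of the changes below was not tested.

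By source name each untreated group held 1 array titled siCtrl and 1 titled siCYLD, split by replicate number. A difference between the titled groups cancels there, so the turned knockdown signs below are not evidence of a reversed effect. The interaction then mostly repeats the difference of the inhibitor pair, which was 1.90 for FN1 and 1.08 for PMEPA1. Its turned signs are therefore not evidence of a reversed interaction either. The difference between titles also adds to the spread within the untreated groups, which lowers all counts of this grouping. Grouping by source names called 0 knockdown genes, 27 inhibitor genes, 0 interaction genes, and 0 in each of siCtrl and siCYLD cells with the inhibitor (104, 2124, 524, 1206 and 1420 at unadjusted p under 0.05). It called 0 knockdown lists and 1 inhibitor list. The direction of the camera test turned for NF-κB targets (median -0.04), mesenchymal genes (-0.03) and proliferation genes (0), and the median alone changed sign for TGF-β pathway components (-0.02) and matrix genes (-0.02). Knockdown differences turned for CYLD (0.01), FN1 (-0.18), INHBA (-0.04), SCG5 (-0.47), TNNI2 (0.1), KIFC1 (0.41), FAT4 (0.19), ABI3BP (0.51), PRR16 (0.04), P3H2 (0.11), ENG (-0.14), TGFB1 (-0.08), DLX2 (-0.05), CXCL2 (-0.02), CXCL8 (-0.44), IKBKE (-0.1), MMP10 (-0.26), CGN (0.12), OVOL2 (0.01), GJB2 (-0.08), S100A9 (0.15), KLF6 (-0.03), LIF (-0.05), CD44 (-0.17), DKK1 (0.1), RNF43 (0.17), SOX9 (-0.05), AJUBA (0.08), CRIM1 (0.04), CCNB2 (0.02), PLK2 (0.07), SESN1 (0.12), HERC6 (0.01), IFIT3 (0.09), ATF3 (-0.09), CTH (0.34), EDEM1 (0.15), PHGDH (0.22), ACAT2 (0.1), INSIG1 (0.13), ADM (0.01), ABCC3 (-0.16), GCLC (0.17), NQO1 (0.14) and PSMD11 (0.07). Interactions turned for FN1 (2.09), SCG5 (0.09), MMP9 (0.65), PMEPA1 (1.05), COL7A1 (0.1), TIMP3 (-0.16), DKK1 (-0.34) and NDRG1 (0.16).

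Outside that grouping 7 of 4016 values of named genes turned and 347 were weaker, and of 836 list values 0 turned, 9 were weaker and 3 stronger. SYT15 turned in the interaction with no offset (-0.87), a smaller offset (-0.81), without untreated siCtrl replicate 1 (-0.76) and without replicate 2 (-0.74), each time because another probe set represented it, and leaving out any 1 array gave -0.76 to 2.68. The same held for FAM81A with the inhibitor under no filter (-0.14) and OVOL2 with the knockdown without _x_at or _s_at probe sets (0.12). ABCC3 turned in the mean of probe sets (-0.14).

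Without the intensity trend the counts were 1219 for the knockdown, 1087 for the inhibitor, 0 for the interaction (1480 at unadjusted p under 0.05), and 35 and 1055 for the inhibitor in siCtrl and siCYLD cells. With no filter the interaction had 33 calls, and the inhibitor 478 in siCtrl and 1819 in siCYLD cells. The interaction had 135 calls under median centring, 95 for the mean of probe sets and 134 without _x_at or _s_at probe sets. Without both arrays with conflicting labels the knockdown had 963 calls in an additive fit and the inhibitor 1257. With the replicate number as a block among untreated arrays the knockdown had 3693 calls, 2754 shared with the test without block, although deviations of equal replicate number correlated at only 0.0447.

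Leaving out 1 array gave 2111 to 2827 calls for the knockdown, 1265 to 2926 for the inhibitor, 288 to 458 for the interaction, 915 to 1682 for the inhibitor in siCtrl cells and 2452 to 3523 in siCYLD cells. It gave 7 knockdown lists throughout, 2 to 4 inhibitor lists, and -0.94 to -0.66 for CYLD. Both ends of the inhibitor range of gene calls came from leaving out 1 inhibitor array, which leaves the inhibitor effect in 1 siRNA alone. Camera with an estimated correlation called 0 lists for the knockdown and 0 for the inhibitor (7 and 0 at unadjusted p under 0.05). The unfolded protein list lost its inhibitor call under median centring, no offset, no trend and no _x_at or _s_at probe sets as well.

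The CYLD probe sets below the filter had differences of -0.50, -0.27 and -0.12. The retention of the knockdown difference under ALK5 inhibitor, in percent of the rises, was 61.5% with 100 genes, 53.5% with 50, 70.9% with 200, 55.4% after quantile normalization and 77.2% with the filter at the 70th percentile. For falls the retention was 37.5%, then 34.8% with 200 genes, 42.8% after quantile normalization and 33.4% at the 70th percentile. That filter gave a correlation of -0.26 between knockdown and inhibitor differences. The robust form was not run for list tests, since camera takes no such option.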
